A study of Escherichia coli with 8 samples.

How the data were processed

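RNA abundance was measured by RNA sequencing in 8 libraries of Escherichia coli MG1655 rph+, 4 from the wild type and 4 from a strain with a temperature-sensitive allele of orn, the gene of oligoribonuclease, an exoribonuclease that degrades very short RNA fragments. The labels give 1 treatment for both strains, 30 min at 42 °C, and name hot phenol extraction, a bacterial rRNA depletion kit and an Ultra II RNA library kit. The group and the replicate letter of each library came from its sample title. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

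Per the submitters' processing notes, cutadapt, Bowtie2 and HTSeq were used, with no role, order or version. The genome build, the annotation and the use of strand in counting are not given in the sources used here. Each library's deposited file held whole-number read counts for 4451 gene symbols, not normalised and with no summary lines for unassigned reads. A further deposited file held the authors' own comparison of the mutant with the wild type made with DESeq2, per the file headers. Its 4432 lines give, per the file headers, a base mean for each gene, which is an average normalised signal over the libraries, a log2 fold change, and a p-value and adjusted p-value as the authors computed them. No count column was left without a sample. Gene symbols were looked up in a RefSeq gene table of assembly ASM584v2, used only for names, gene types, gene lengths and neighbourhood. Of the 4451 symbols, 4237 matched a current symbol, 200 matched a synonym and 14 matched nothing. No coordinates are reported, because the build behind the counts is not given.

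Differential abundance was tested in R 4.3.3 with edgeR 4.0.16. Genes passed edgeR's filterByExpr, library totals were scaled by TMM factors, and a robust quasi-likelihood F test compared the groups with no covariate. Benjamini-Hochberg adjustment ran over the 4195 genes tested, and a gene was called at an adjusted p under 0.05. Of the 256 genes not tested, 18 had no count in any library. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. Levels are CPM, the usual depth-scaled counts, computed here from the counts and TMM-scaled totals, given as mean ± SD over n = 4 libraries, and log2 fold changes are mutant minus wild type ± SE. Total counts ran from 8443732 to 27219062 per library, and the common biological coefficient of variation was 17.2%.

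Before the data were examined, 34 gene lists were fixed from general knowledge, and the tRNA genes of the reference table made a 35th, so that 35 lists were tested. A list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 35 lists. Camera with an estimated correlation and fry were run beside it. The rule for the genes to be named was also fixed in advance. It took orn, and the 10 highest and 10 lowest log2 fold changes among called genes with a mean count of at least 50 and no overlap between the 4 mutant and the 4 wild-type libraries. It further took up to 4 called members, by lowest adjusted p, of each list that was called or held at least 3 called members. For the lists on curli and biofilm, cyclic di-GMP enzymes, RNA decay and orn neighbours it took up to 3 members whether called or not. The rule gave 131 genes, and genes outside it are said to have been chosen after their values were seen, except further members of fixed lists.

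The test was checked on simulated counts drawn from the real means, library sizes and dispersions, with 4195 genes simulated, 4177 of them past the filter of the simulated fit, and 50 genes changed at each fold. The genes changed at each fold were drawn only from genes with a mean count of at least 50. Recovery of such folds in genes with lower counts was therefore not tested. It recovered 16% of the genes changed 1.25-fold, 56% at 1.5-fold, 90% at 2-fold and 98% at 4-fold. Of 3961 unchanged genes in the fit, 10 were called, which was 6.49% of the 154 calls. The other calls were 130 changed genes and 14 of the 16 members of a list shifted by 0.5 on the log2 scale, which was the only list called. The real data gave 1456 calls, and with fewer calls the adjusted cutoff is stricter. Recovery of small folds may therefore be higher in the real data.

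The alternatives planned in advance were DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter of 50 counts in 4 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate letter, the 20 most abundant genes left out, and each library left out in turn. Chosen after seeing the data were library totals with no scaling factor, rRNA genes left out, wild-type libraries B and D left out together, and every library thinned to the smallest total. All 35 ways to divide the 8 libraries into 4 and 4 were fitted. Library pairs within a group differed by a chi-square of 28.5 to 77.7 per degree of freedom, so no pair was a repeat of 1 library. The list members micL (in 2 lists) and sroC had no symbol in the files and were not analysed here. Genes with near-identical copies, overlapping genes and antisense pairs are reported as uncertain, since the counting could not be shown to separate them.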

Results

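The series measured RNA abundance in Escherichia coli MG1655 rph+ and in a strain carrying a temperature-sensitive allele of orn, to find RNAs that depend on oligoribonuclease. Cultures in early log phase in a rich defined medium were held at 42 °C for 30 min before harvest. All libraries came from this condition. Differences that the strains already had before the shift therefore cannot be told apart from those that arose at 42 °C. Each strain had 4 libraries, named here by strain and replicate letter. Wild-type libraries A to D held 14786589, 19793358, 8443732 and 24440812 counts, and mutant libraries A to D held 23242601, 16294562, 27219062 and 20904629. Wild-type library C was therefore the shallowest of the 8. Ribosomal RNA took 0.491% of the counts in wild-type library B, 0.0949% in wild-type library D and 0.104% in mutant library C, against 0.0131% to 0.0235% in the other 5.

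The targeted gene, orn, did not differ between the strains in RNA level, as a temperature-sensitive allele need not change it. Its level was 63.3, 67.3, 147.1 and 71.8 CPM in wild-type libraries A to D and 87.2, 109.4, 106.4 and 107.7 CPM in mutant libraries A to D (log2 fold change 0.24 ± 0.29, adjusted p = 0.587 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Wild-type library C decided this value: without it the log2 fold change was 0.61 (adjusted p = 0.000111). With wild-type libraries A, B or D left out it was 0.11, 0.14 or 0.16, and with B and D both left out it was -0.02. The RNA level of orn thus gives no check of the labels.

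Between the strains, 647 genes were higher and 809 were lower in the mutant, out of 4195 tested, or 34.7%. At least a 2-fold difference was found for 88 of the higher and 78 of the lower genes. Below flu, which was high in 2 mutant libraries only, the highest rule-selected genes were those of enterobactin synthesis and uptake, uracil salvage (upp) and adenosine deaminase (add), and the lowest included the cold-shock family gene cspE, the phosphate transporter gene pitA and the gluconate transporter gene gntT. In 1442 genes (34.4%) the 4 mutant libraries did not overlap the 4 wild-type libraries, where chance gives 2.86%. The balance of directions depended on the scaling. Higher genes made up 44.4% of the calls with TMM factors, 54.7% with upper-quartile factors (812 higher, 672 lower) and 64.3% with library totals alone (993 higher, 551 lower), which moved the median log2 fold change of all genes from 0.015 to 0.127.

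Iron acquisition genes rose. Of 27 tested members of the Fur regulon of iron uptake, 16 rose, none fell and 11 were not called, with 19 higher adjusted over the list alone. The isochorismate synthase gene entC, the first step of enterobactin synthesis, rose from 6.34 ± 2.75 to 84.9 ± 4.04 CPM (log2 fold change 3.73 ± 0.29, 13.3-fold). The catecholate receptor gene cirA rose from 22.6 ± 8.57 to 218.3 ± 8.99 CPM (3.27 ± 0.27), and the ferric enterobactin receptor gene fepA from 21.8 ± 4.72 to 133.7 ± 6.33 CPM (2.61 ± 0.13). entE, entB, entA, fes and fiu rose by log2 fold changes of 3.03, 3.01, 2.50, 2.40 and 2.40. Not called were tonB at -0.09, feoA at 0.10 and feoB at 0.13. Wild-type library D lay above the other wild-type libraries for this list: against the wild-type mean its members averaged 0.54 on the log2 scale, the other wild-type libraries -0.25, -0.19 and -0.10, and the mutant libraries 1.42 to 1.51. Without library D, 24 members were called higher. The list was called higher by camera, with adjusted p = 0.451 with an estimated correlation.

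Pyrimidine synthesis and salvage genes moved both ways. Of 15 tested, 9 rose, 5 fell and 1 was not called, with the same counts, 9 and 5, adjusted over the list alone. The uracil salvage pair upp (uracil phosphoribosyltransferase) and uraA (uracil permease) rose by 2.75 ± 0.12 and 2.33 ± 0.08, the latter from 137.2 ± 17.3 to 691.4 ± 16.3 CPM. The cytosine permease gene codB rose from 196.7 ± 19.8 to 556.7 ± 23.1 CPM and the carbamoyl phosphate synthase gene carB by 1.12 ± 0.07. pyrC fell by 1.09 and cmk by 0.88. Camera called the list higher, with adjusted p = 0.430 with an estimated correlation. Purine synthesis genes were split as a list, with 4 higher, 5 lower and 6 not called of 15 and the same counts, 4 and 5, adjusted over the list alone (camera adjusted p = 0.755); 3 were lower without wild-type library B or C or mutant library A or C, and library totals alone gave 7 higher and 3 lower. Within it guaB, guaA and purC rose by 1.13 ± 0.06, 0.91 ± 0.07 and 1.05 ± 0.08. The gene of the purine repressor, purR, fell by 1.35 ± 0.06, from 558.8 ± 23.8 to 218.6 ± 10.8 CPM. The purine synthesis genes purF, purN, purE and purM were called lower, at -0.43, -0.43, -0.24 and -0.20. Outside the lists, add rose from 96.9 ± 8.81 to 537.8 ± 30.3 CPM (2.47 ± 0.08, adjusted p = 3.8e-12).

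**Figure D1:**
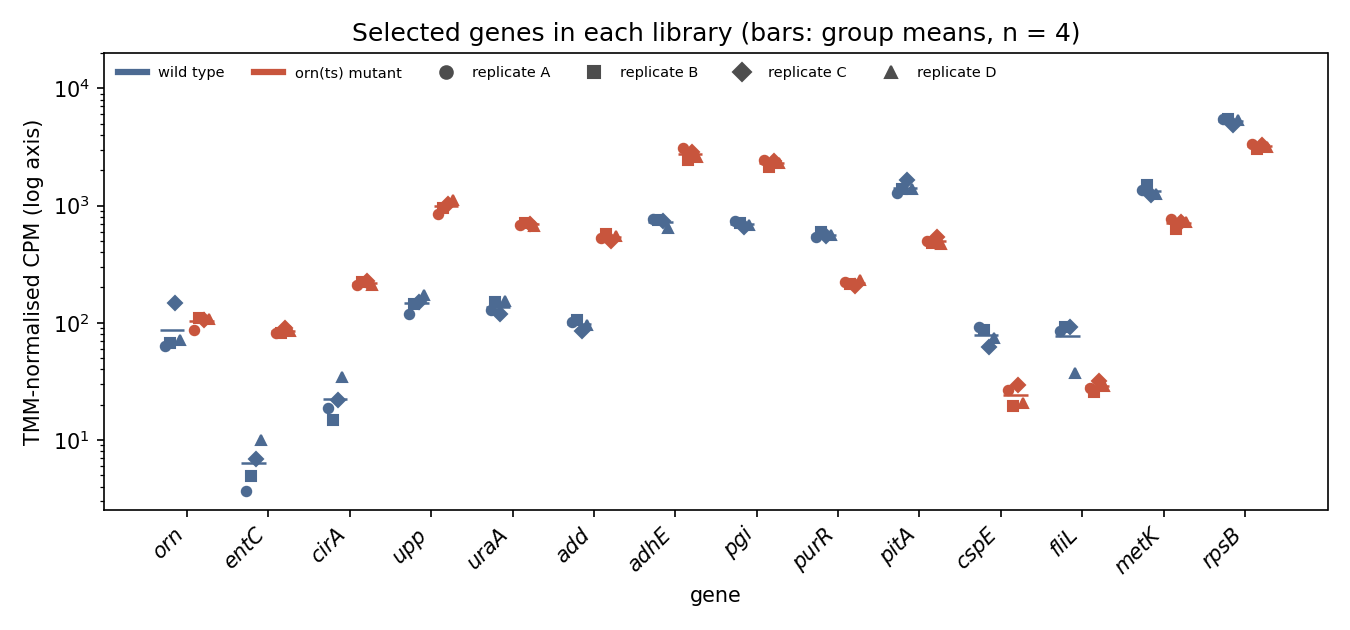
TMM-normalised CPM (log axis) of 14 named genes in each of the 4 wild-type and 4 mutant libraries, with bars at the group means and marker shapes for the replicate letters. For entC the mutant libraries sit between 82.0 and 90.7 CPM and the wild-type libraries between 3.65 and 9.94, while for orn wild-type library C at 147.1 CPM stands above all of the other 7.

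Glycolytic genes rose. Of 17 tested, 11 rose, 2 fell and 4 were not called, and adjusted over the list alone 11 were higher and 3 lower. The phosphoglucose isomerase gene pgi rose from 694.7 ± 37.7 to 2317 ± 138 CPM (1.74 ± 0.07), gpmA by 1.35 ± 0.06, the phosphofructokinase gene pfkA by 1.23 ± 0.05 and the enolase gene eno by 1.05 ± 0.07. fbaB and the glucose transporter gene ptsG fell by 0.78 and 0.56. As a list they were called higher, with adjusted p = 0.430 with an estimated correlation. Of 30 genes of anaerobic respiration and fermentation, 7 rose, 5 fell and 18 were not called, with 7 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.460). Among them the alcohol dehydrogenase gene adhE rose by 1.92 ± 0.08, from 726.1 ± 53.8 to 2744 ± 293 CPM, nirB by 1.28 ± 0.09 and pflB by 0.60 ± 0.08, while the formate channel gene focA fell by 0.76 ± 0.08. In the tricarboxylic acid cycle 5 of 16 genes rose and 3 fell, the same counts as adjusted over the list alone, with mdh, gltA and acnB rising by 0.86, 0.76 and 0.50 and sucA falling by 0.39 (list camera adjusted p = 0.755). Of 28 respiratory genes of ATP synthase, NADH dehydrogenase and the cytochrome oxidase, 3 rose and 5 fell, also 3 and 5 adjusted over the list alone. The gene of the non-coupling NADH dehydrogenase, ndh, rose by 1.68 ± 0.07 from 1206 ± 64.7 to 3872 ± 182 CPM, while nuoA, atpI and atpC fell by 0.44, 0.59 and 0.38 (list camera adjusted p = 0.359). Without mutant library C 1 of them was higher, and with library totals alone 6 were higher and 5 lower.

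Genes of the oxidative stress list (SoxRS and OxyR) rose in part. Of 20 tested, 10 rose, 1 fell and 9 were not called, and adjusted over the list alone 12 were higher and 2 lower. The alkyl hydroperoxide reductase gene ahpF rose by 1.61 ± 0.07, while ahpC, of the same enzyme, rose by 0.22 ± 0.07, from 2975 ± 249 to 3470 ± 195 CPM. fldA rose by 0.60 ± 0.09, fumC by 0.56 ± 0.07 and the glutathione reductase gene gor by 0.30 ± 0.06. The catalase gene katG, at 0.09, was not called. Without wild-type library C 2 members were lower. Several risen members also answer to iron or to Fur, among them sodA at 0.91, sufA at 0.90 and sufC at 0.78. Camera called them higher together, with adjusted p = 0.170 with an estimated correlation.

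Flagellar and chemotaxis genes fell. Of 50 tested, 34 fell, none rose and 16 were not called, with 39 lower adjusted over the list alone. The master regulator gene flhC fell from 117.2 ± 3.24 to 66.0 ± 5.72 CPM (by 0.83 ± 0.08), the motor genes motA and motB by 0.83 ± 0.10 and 0.84 ± 0.10, flgJ by 0.94 ± 0.13 and fliL by 1.42 ± 0.29. cheA, cheY, cheW, cheZ and tar, at log2 fold changes from -0.16 to 0.09, were not called. Wild-type library D lay near the mutant level here: the list averaged -0.53 in it against the wild-type mean, 0.09, 0.32 and 0.12 in wild-type libraries A to C, and -0.73 to -0.62 in the mutant libraries. The flagellar sigma factor gene fliA measured 90.9 CPM in library D against 220.5 to 247.7 in the other wild-type libraries and 79.5 to 98.6 in the mutant. The number called was 44 without library D, 21 without wild-type library B, 21 without mutant library A and 20 without mutant library D. The list was called lower, with adjusted p = 0.574 with an estimated correlation.

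Most ribosomal protein genes fell. Of 54 tested, 42 fell, none rose and 12 were not called, with 47 lower adjusted over the list alone and a median log2 fold change of -0.51. rpsB fell from 5270 ± 289 to 3201 ± 131 CPM (by 0.72 ± 0.07), rpsI by 0.83 ± 0.09, rplA by 0.55 ± 0.07 and rpmH by 0.95 ± 0.09. With library totals alone the median was -0.39 and 41 were called lower. The list was called lower, with adjusted p = 0.415 with an estimated correlation. Among 35 genes of translation factors and aminoacyl-tRNA synthetases, 15 fell, 4 rose and 16 were not called, with 16 lower and 5 higher adjusted over the list alone. The glycyl-tRNA synthetase genes glyQ and glyS fell by 0.91 ± 0.05 and 0.93 ± 0.06 and infC by 0.58 ± 0.06, while lysU, the heat-inducible lysyl-tRNA synthetase gene, rose by 0.76 ± 0.07. Its members tufA and tufB are near-identical copies, so their values of -0.29 and 0.07 are uncertain. This list was called lower (camera adjusted p = 0.021), with adjusted p = 0.687 with an estimated correlation, and its call ended without mutant library B (0.0819), with upper-quartile factors (0.0618), with the stricter filter (0.0520) and with library totals alone (0.211), where 10 members were higher and 9 lower.

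Of 84 tRNA genes, 18 fell, none rose and 66 were not called, with 16 lower adjusted over the list alone. hisR fell by 1.19 ± 0.12, argX by 0.99 ± 0.12 and leuU by 0.78 ± 0.09, from levels of 48.5 to 115 CPM in the wild type. The value of leuT, lower by 1.36 ± 0.11, is uncertain because leuP, leuQ and leuV are near-identical copies. glnX and glnV, lower by 1.59 ± 0.24 and 1.64 ± 0.29, are near-identical copies and their separate values are uncertain. The list was called lower, with adjusted p = 0.574 with an estimated correlation, and without wild-type library C its camera adjusted p was 0.0503 and its median -0.11, against -0.18 with all libraries. Without wild-type library C or mutant library A 1 tRNA gene was higher.

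Genes of several amino acid pathways fell together. All 8 histidine biosynthesis genes fell, also 8 adjusted over the list alone, by 0.25 to 0.48, with hisF down by 0.48 ± 0.06, hisG by 0.47 ± 0.07, hisC by 0.40 ± 0.06 and hisD by 0.38 ± 0.06 (adjusted p = 0.415 with an estimated correlation). Of 11 methionine genes 7 fell and 4 were not called, also 7 adjusted over the list alone (adjusted p = 0.170 with an estimated correlation). The methionine transporter genes metN and metI fell by 1.00 ± 0.07 and 0.89 ± 0.07 and the S-adenosylmethionine synthetase gene metK by 0.90 ± 0.08, from 1337 ± 129 to 714.8 ± 62.0 CPM. Among 14 branched-chain genes 8 fell and 6 were not called, 9 adjusted over the list alone, with ilvB lower by 0.79 ± 0.08 and leuA, leuB and leuC by 0.44, 0.43 and 0.43 (adjusted p = 0.451 with an estimated correlation). For aromatic amino acids 8 of 20 fell and 12 were not called, also 8 adjusted over the list alone, led by aroP at -0.54 ± 0.07, trpE at -0.44 ± 0.09, aroD at -0.38 ± 0.09 and aroK at -0.24 ± 0.06. This call (camera adjusted p = 0.030, adjusted p = 0.523 with an estimated correlation) ended with upper-quartile factors (0.0784), the stricter filter (0.0543), thinned libraries (0.05504) and library totals alone (0.211, 2 members lower). With library totals alone the calls of aroD (adjusted p = 0.0647) and aroK (0.165) were lost. The members lower were 5 without wild-type library A, mutant library B or mutant library D. Arginine genes were not called as a list (camera adjusted p = 0.996), with 1 higher, 1 lower and 7 not called of 9, also 1 and 1 adjusted over the list alone, and none was lower without wild-type library B or C or any mutant library. Of 15 cysteine and sulfate genes 2 rose, cysA by 0.82 and cysW by 0.73, and 13 were not called, with 1 higher adjusted over the list alone (camera adjusted p = 0.076). The cysteine list averaged 0.68 in wild-type library B and -0.32 to -0.06 in the other wild-type libraries, and 6 members were higher without library B, 5 with library totals alone, and 1 without wild-type library A, C or D or mutant library A, C or D. Without library B the list was called higher (0.00125), as it was without mutant library A (0.0423) or B (0.0432).

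Sugar catabolism genes under CRP were mixed, with 14 lower, 6 higher and 18 not called of 38, and 15 lower and 6 higher adjusted over the list alone. The ribose genes rbsA and rbsC fell by 1.14 ± 0.09 and 0.99 ± 0.11 and the galactitol gene gatC by 0.87 ± 0.07, while the sorbitol gene srlD rose by 1.09 ± 0.11. The list was called lower (camera adjusted p = 0.034), with adjusted p = 0.569 with an estimated correlation. The number higher was 3 without mutant library D, and the camera adjusted p was 0.0509 without mutant library C and 0.0532 with the stricter filter.

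**Figure D2:**
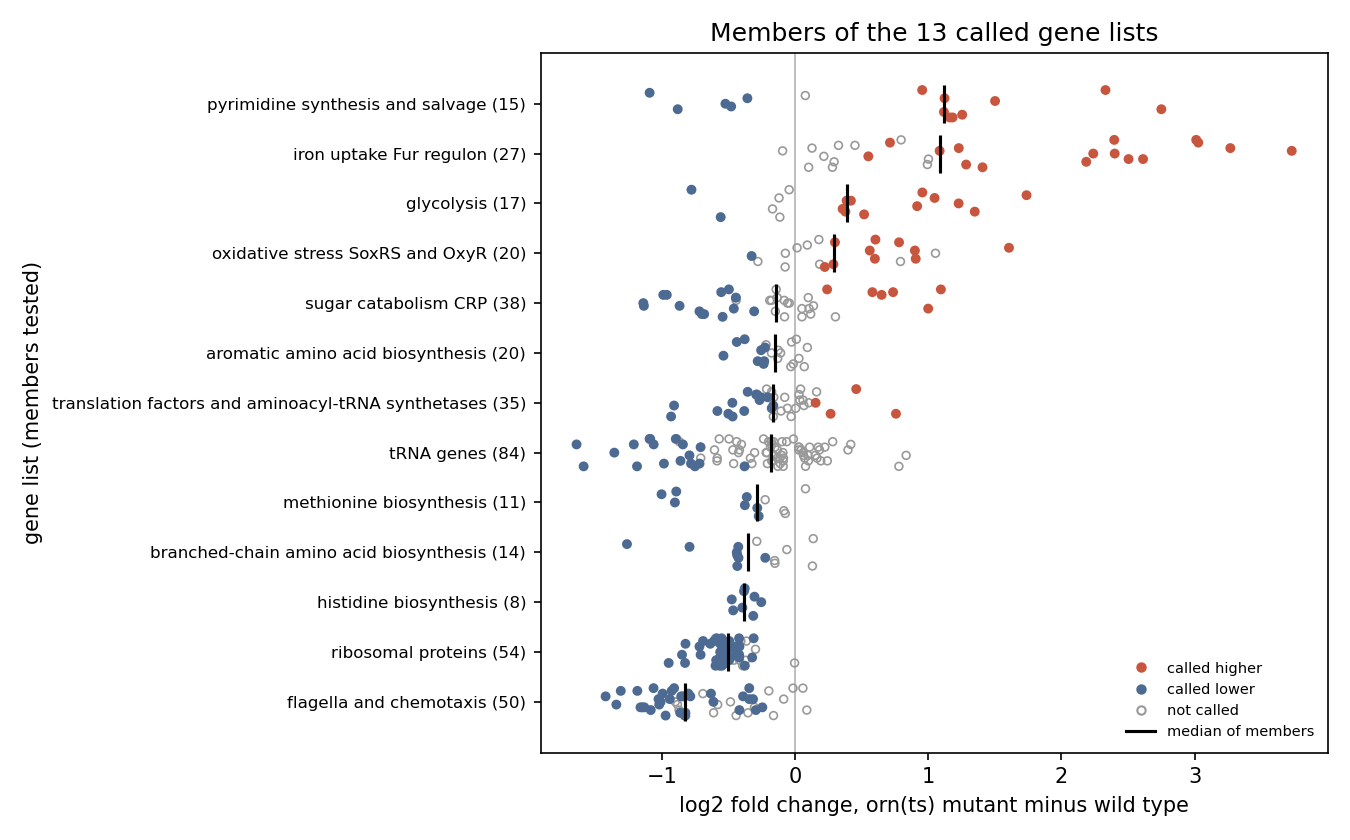
Log2 fold change (mutant minus wild type) of every tested member of the 13 gene lists that camera called with a preset correlation, 1 point per gene, with filled points for called genes and bars at list medians. The medians run from -0.83 for flagella and chemotaxis to 1.12 for pyrimidine synthesis and salvage.

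In the following stress lists called members moved both ways, except for acid resistance and cold shock, and camera called none of the lists. Fry, which does not compare a list with other genes, called SOS, Cpx and acid resistance lower (adjusted p = 0.00777, 0.0114 and 0.0352). Of 20 heat-shock genes 6 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.755): the disaggregase gene clpB rose by 0.69 ± 0.07 and clpP by 0.41 ± 0.06, while the protease genes ftsH and lon fell by 0.52 ± 0.07 and 0.37 ± 0.07. With library totals alone 10 heat-shock genes were higher. In the sigmaE list 3 of 15 rose and 4 fell (4 and 4 adjusted over the list alone, 0.996), with the periplasmic protease gene degP up by 1.27 ± 0.08 and rseA by 0.39 ± 0.06, and fkpA and skp down by 0.58 ± 0.10 and 0.28 ± 0.06. Without wild-type library B or mutant library C 2 of these were lower, and with library totals alone 5 were higher and 2 lower. For the Cpx list 2 of 11 rose and 3 fell (3 and 3 adjusted over the list alone, 0.851), among them dsbA at 0.46, yccA at 0.34, cpxA at -0.34 and ldtC at -0.64. For Rcs and colanic acid 1 of 22 rose and 1 fell (0 and 0 adjusted over the list alone, 0.755), and for phage shock 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone, 0.755). No Rcs gene was lower without wild-type library A, B or D or mutant library B, C or D, none was higher without wild-type library D or mutant library D, and 2 phage shock genes were lower without wild-type library D. Among 18 RpoS genes 4 rose and 4 fell (5 and 4 adjusted over the list alone, 0.755). rpoS itself fell by 0.64 ± 0.06 and tktB by 0.60 ± 0.10, while dps and wrbA rose by 0.84 ± 0.10 and 0.69 ± 0.11. Of 13 acid resistance genes 5 fell and 8 were not called (5 adjusted over the list alone, 0.074), including mdtE at -0.73, hdeA at -0.69, hdeB at -0.67 and mdtF at -0.48. That list was called lower without wild-type library A (0.0422), wild-type library C (0.0385) or mutant library B (0.0422), and also with limma-voom (0.0433) and with library totals alone (0.0358). In the SOS list 6 of 23 fell and 2 rose (6 and 2 adjusted over the list alone, 0.460), with ftsK down by 0.72 ± 0.05 and uvrB by 0.43 ± 0.05 and recA and yebG up by 0.36 ± 0.05 and 0.54 ± 0.10. Of 7 cold-shock genes 2 fell, also 2 adjusted over the list alone (0.755): cspE fell by 1.70 ± 0.15, to 24.2 ± 4.78 CPM, and cspC by 0.60. With library totals alone 4 cold-shock genes were higher and 2 lower.

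RNA decay genes, the class orn belongs to, gave 5 higher, 5 lower and 12 not called of 22, also 5 and 5 adjusted over the list alone (camera adjusted p = 0.755). The exoribonuclease genes rnb (RNase II) and rnd (RNase D) fell by 0.68 ± 0.07 and 0.72 ± 0.08 and the RNase P protein gene rnpA by 0.74 ± 0.09, while pnp (polynucleotide phosphorylase) rose by 0.25 ± 0.06. The pnp call was lost with wild-type libraries B and D left out (adjusted p = 0.075), and with library totals alone 11 of the list were higher and 3 lower. Of 27 small and housekeeping RNAs 5 fell, none rose and 22 were not called, with 4 lower adjusted over the list alone (camera adjusted p = 0.251). These included glmZ at -1.05 ± 0.23 and the antisense RNAs sibB at -2.81 ± 0.47, sibC at -1.20 ± 0.25 and sibD at -1.05 ± 0.32. The sib RNAs overlap short toxin genes on the other strand and have near-identical copies, and sibB had 3.29 CPM in the wild type, so these values are uncertain. The sibD call was lost without wild-type library C (log2 fold change -0.67, adjusted p = 0.0508) or mutant library D (0.0561), and without mutant library D 3 of the list were lower.

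Enzymes that make or break cyclic di-GMP, a second messenger whose breakdown ends in the dinucleotide that oligoribonuclease clears, were mostly not called. Of 25 genes, 4 rose, 3 fell and 18 were not called, the same 4 and 3 adjusted over the list alone (camera adjusted p = 0.755), with gmr at 0.63 ± 0.10, yeaJ at 0.47 ± 0.11, dosP at 0.50 ± 0.12 and yneF at -0.47 ± 0.10. With library totals alone 7 were higher and 1 lower. In the curli and biofilm list 9 of 22 rose and 3 fell, also 9 and 3 adjusted over the list alone (camera adjusted p = 0.283). The polysaccharide export gene pgaA rose by 1.22 ± 0.15 and pgaC by 0.94 ± 0.22, from 5.76 and 4.21 CPM, while bssS and csgC fell by 1.00 ± 0.16 and 1.98 ± 0.47. For csgC the levels were low, 3.53 ± 1.69 CPM in the wild type and 0.88 ± 0.50 in the mutant. Its libraries overlapped between the strains, with 1.08 CPM in wild-type library D and 1.62 in mutant library B. The number higher was 4 without wild-type library A, wild-type library B or mutant library B, 5 without mutant library A or D, and 6 without wild-type library D or mutant library C. Type 1 fimbriae gave 2 lower and 7 not called of 9, with 1 lower adjusted over the list alone (camera adjusted p = 0.460), and 4 were lower without wild-type library C or mutant library A, and 1 without any of the other 6 libraries. None of the 22 genes of the toxin-antitoxin list was called by edgeR (0 also adjusted over the list alone, 0 at an unadjusted p under 0.05), nor by limma-voom. DESeq2 called 1 of them, edgeR with library totals alone called 1 and edgeR without wild-type library A called 1 (list camera adjusted p = 0.910). The short toxin genes ibsB and ibsD, which overlap sib RNAs, were outside this list and were chosen after their values were seen. Both were called lower by edgeR, at log2 fold changes of -2.75 (adjusted p = 0.000427) and -1.199 (adjusted p = 0.0109). Their levels in the wild type were 3.18 and 5.01 CPM, and like those of the sib RNAs their values are uncertain. Among 7 neighbours of orn 1 rose, psd by 0.52 ± 0.07, and 3 fell, amiB by 0.21 ± 0.06, tsaE by 0.24 ± 0.09 and rsgA by 0.17 ± 0.06, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.755). The calls of amiB, tsaE and rsgA were lost with library totals alone, at adjusted p = 0.323, 0.318 and 0.540, and with upper-quartile factors, at 0.0630, 0.104 and 0.149. Those of tsaE and rsgA were also lost with no filter (0.0573 and 0.0546) and with thinned libraries (0.0816 and 0.0532), and that of amiB with wild-type libraries B and D left out (0.0836). The tsaE call was also lost without wild-type library A (0.0911), C (0.0527) or D (0.0523) or mutant library A (0.105), B (0.0939), C (0.0502) or D (0.0562). The rsgA call was lost without wild-type library A (0.0652) or C (0.0817) or mutant library A (0.0803), B (0.0841) or C (0.125). The neighbours lower were 1 without wild-type library A or C or mutant library A, B or C.

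Without calls as lists, several lists had a median and a mean of opposite sign. Cold shock had a median of 0.06 and a mean of -0.26, RNA decay 0.11 and -0.04, purine synthesis -0.03 and 0.09, the tricarboxylic acid cycle -0.08 and 0.06, sigmaE -0.06 and 0.02, cyclic di-GMP enzymes -0.00 and 0.09, arginine -0.04 and 0.00, and toxin-antitoxin 0.04 and -0.04. The camera test pointed higher for RNA decay, purine synthesis, the tricarboxylic acid cycle, sigmaE, cyclic di-GMP enzymes and toxin-antitoxin, and lower for cold shock and arginine. With an estimated correlation none of the 35 lists was called in either direction; at an unadjusted p under 0.05 it gave 1 higher and 3 lower, and fry, which does not compare a list with other genes, gave 7 higher and 12 lower.

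Among the 10 lowest rule-selected genes, pitA, the gene of a phosphate transporter, fell from 1422 ± 157 to 496.1 ± 28.4 CPM (by 1.52 ± 0.08, adjusted p = 7.7e-10). yjiY, a pyruvate transporter gene, fell by 1.40 ± 0.08 and gntT by 1.38 ± 0.11. Also among them, besides cspE, glnV, glnX and fliL given above, were the small RNA gene psrD at -1.73 ± 0.36, yecR at -1.66 ± 0.34 and ymdA at -1.37 ± 0.30, the latter 2 from 13.8 and 14.3 CPM in the wild type. The ymdA call was lost with limma-voom (adjusted p = 0.0621).

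The highest rule-selected fold change, that of flu, the gene of the surface adhesin antigen 43, came from 2 mutant libraries. flu measured 7156 and 3896 CPM in mutant libraries A and D, 209 and 171 in mutant libraries B and C, and 105 to 161 in the wild type (log2 fold change 4.54 ± 1.39, adjusted p = 0.048). Leaving out any wild-type library, or mutant library A or D, ended the call (adjusted p from 0.0964 to 0.116). So did limma-voom (0.189), no filter (0.0504), the replicate block (0.315) and leaving out wild-type libraries B and D (0.248). Reads of flu can overlap the small RNA isrC. Another departure was in wild-type library D, where the zinc uptake genes zinT and znuA measured 1045 and 1857 CPM against 5.76 to 6.26 and 64.8 to 126 in the other wild-type libraries, and 5.72 to 10.5 and 57.8 to 105.5 in the mutant. The 2 genes were chosen after their values were seen, and neither was called between the strains (adjusted p = 0.135 for znuA).

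**Figure D3:**
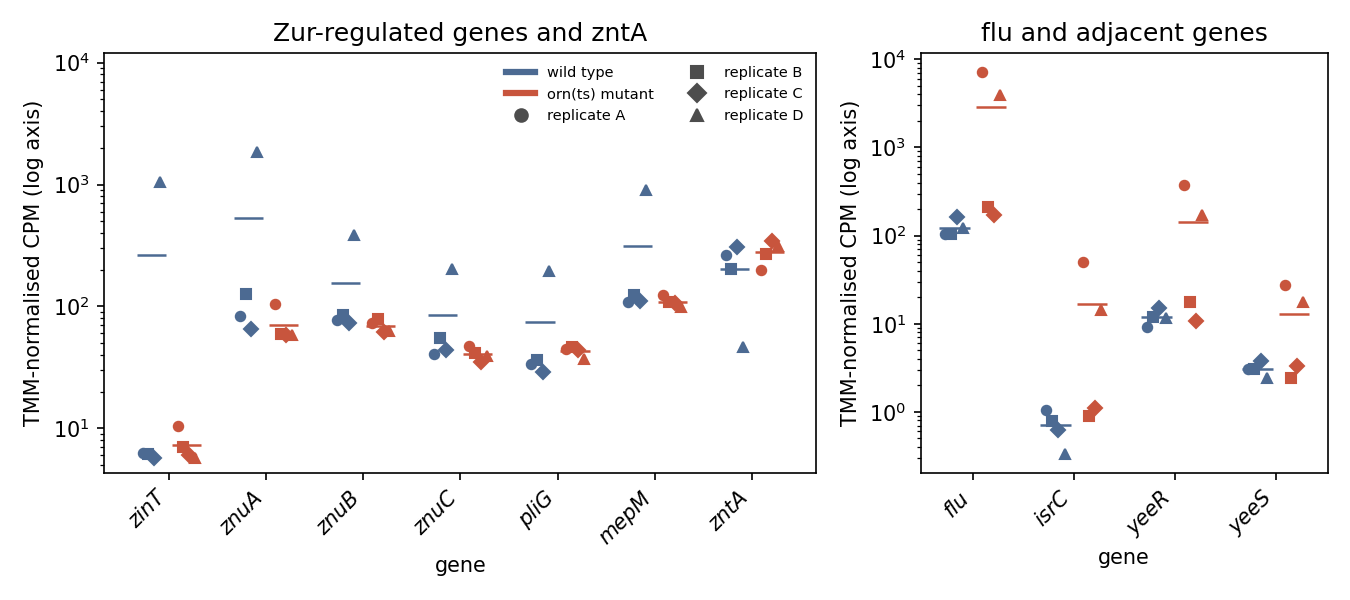
TMM-normalised CPM (log axis) in each of the 8 libraries for 6 genes under the zinc repressor Zur and the zinc exporter gene zntA, and for flu and 3 adjacent genes, with bars at group means. Wild-type library D stands above the other 7 for zinT (1045 CPM) and below them for zntA (46.2 CPM), and mutant libraries A and D stand above the other 6 for flu (7156 and 3896 CPM).

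The authors' deposited table called 1556 genes at an adjusted p under 0.05, 702 higher and 854 lower, of which 78 and 63 changed at least 2-fold. Of these calls, 641 higher and 805 lower genes were also called by edgeR here, and none was called in the opposite direction. Across the 4194 genes in both, which are not independent replicates, the log2 fold changes had a Spearman rho of 0.997. Fold changes of variable genes were smaller in the authors' deposited table, with flu at 1.05 there and 4.54 here and entC at 3.19 there and 3.73 here. For the steady genes add, upp and pitA the authors' deposited table gave 2.43, 2.68 and -1.50, beside 2.47, 2.75 and -1.52 from edgeR.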

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

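The test of a wrong label for wild-type library D and the test of flu promoter switching were chosen only after the result was seen. In each strain, the highest or lowest of 4 libraries was compared with the others by Dixon's criterion for 4 values, over 131 named genes, 3 library measures and 13 list means. It picked 19 of 294 sets of 4, where chance gives about 1 in 20, or 14.7, so most of these values may be chance. That figure is approximate, because most of the genes were named for a low adjusted p and the sets are not independent. Wild-type libraries C and D held 6 and 5 of the 19. Among the alternatives, leaving out wild-type library C moved the log2 fold change of orn from 0.24 to 0.61.

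Wild-type library C was high for orn (147.1 CPM, others 63.3 to 71.8), guaA (2995, others 2708 to 2731), gor (474, others 405 to 417) and srlD (20.7, others 15.4 to 15.9), low for rpsB (4838, others 5376 to 5439), and high for the branched-chain list mean (0.063 on the log2 scale, others -0.022 to -0.020). Wild-type library D was low for adhE (646 CPM, others 745 to 761), eno (1838, others 2037 to 2073), fliL (37.5, others 85.5 to 92.8) and sibC (4.48, others 7.89 to 8.02), and high for aroD (75.2, others 66.3 to 67.3). Wild-type library B was high for mdtE (33.5 CPM, others 22.7 to 23.5). In the mutant, library A was low for orn (87.2 CPM, others 106.4 to 109.4) and rbsC (40.3, others 49.6 to 51.1). Mutant library B was high for srlD (38.5 CPM, others 34.8 to 34.9), dsbA (920.4, others 688 to 716) and gatC (72.1, others 66.8 to 66.9). Mutant library D was high for hisD (268.8 CPM, others 242 to 246), and mutant library C held 0.104% rRNA against 0.0135% to 0.0235%.

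In wild-type library D, 6 tested genes under the zinc repressor Zur stood above the mean of the other wild-type libraries: zinT 172-fold, znuA 20.3-fold, mepM 7.81-fold, pliG 5.93-fold, znuB 4.88-fold and znuC 4.34-fold. A mutant library under a wild-type label is argued against by the 197 genes changed at least 2-fold without library D. Over them its median position between the other wild-type libraries (0) and the mutant (1) was 0.168, with quartiles of 0.0149 and 0.550. The SE of this median, 0.033, treats the genes as independent, which co-regulated genes are not. High zinT was particular to library D, so it does not bear on the strain of that library. A lack of zinc in that sample predicts a low level of the zinc-induced exporter gene zntA, which measured 46.2 CPM in library D and 201 to 305 CPM in the other wild-type libraries, consistent with such a shortage as a hypothesis. It leaves open why iron and flagellar genes of library D also lay toward the mutant level.

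The genes flu, isrC, yeeR and yeeS were high in mutant libraries A and D. A difference of over 4-fold across many genes between those libraries and B and C is argued against. Only these 4 of 3637 genes separated A and D from B and C by over 4-fold, and 0 genes separated the other pairings. A broad difference of smaller size was not tested. Switching of the flu promoter between on and off states, known for this gene, stays open: isrC, yeeR and yeeS were at least 5.34 times higher in A and D than in B and C, but they were picked because they showed the pattern, so this ratio decides nothing. Of the genes beyond them, cbeA measured 2.32 and 2.21 CPM in A and D against 3.74 and 2.23 in B and C, and yeeT 2.02 and 1.89 against 0.948 and 0.899. Whether orn has any part in it stays untested.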

How the results depend on the processing

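The settings with library totals alone, without rRNA genes, without wild-type libraries B and D, and with thinned libraries were chosen only after the result was seen. Across all settings none of the 1456 genes was called in the opposite direction, where a change of sign without a call was not counted. Calls kept were fewest with wild-type libraries B and D left out (1090), without mutant library D (1180) and with library totals alone (1198). Of 130 named genes besides orn 121 kept direction and call in every setting that tested them. The stricter filter removed sibB and csgC, and leaving out the most abundant genes removed rplA. The named genes that changed were tsaE (12 settings changed), flu (10), rsgA (10), amiB (3), sibD (2), aroD, aroK, pnp and ymdA (1 each). Of 13 lists 9 kept their call in every setting with the preset correlation, and none kept it with an estimated one; translation and aromatic amino acids lost it in 4, sugar catabolism in 2 and tRNA genes in 1. With library totals alone 993 genes were higher, against 647, since that setting moved the median log2 fold change of all genes from 0.015 to 0.127. The log2 fold change of orn was -0.022 with wild-type libraries B and D left out (adjusted p = 0.973, and 0.242 to 0.973 over the settings other than leaving out single libraries) and 0.11 to 0.61 with single libraries left out; the value rests on wild-type library C. Leaving out single libraries gave 527 to 650 higher and 681 to 792 lower genes, 86 to 99 and 72 to 99 at 2-fold, and 4 to 5 higher and 8 to 10 lower lists. Camera with an estimated correlation called 0 lists higher and 0 lower, with estimated correlations from -0.00585 (methionine) to 0.617 (iron uptake) over the called lists. Fry, which does not compare a list with other genes, called 7 higher and 12 lower. The replicate letters did not pair the libraries: deviations of same-letter libraries correlated at 0.119, -0.139, -0.147 and 0.012 for A to D, and not every library correlated best with its own letter. With the replicate block 636 genes were higher and 784 lower, and the calls of flu (adjusted p = 0.315), tsaE (0.0610) and rsgA (0.0505) were lost. In data simulated at the real library sizes, but with fewer changed genes than were called here, 16% of changes of the smallest simulated fold were recovered. Those changes were placed only in genes with a mean count of at least 50. With every library thinned to the smallest 610 genes were higher and 766 lower.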

Other observations

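The tests on PurR and all genes named in the first paragraphs were chosen only after the result was seen. Of 139 genes that passed the naming criteria with at least a 2-fold change, 79 were in no list, 39 higher and 40 lower. In the deoxyribonucleoside operon the downstream genes deoB and deoD rose from 541.0 ± 15.1 to 2649 ± 103 CPM and from 713.3 ± 13.4 to 2182 ± 56.3 CPM (log2 fold changes 2.29 ± 0.06 and 1.61 ± 0.06), while the upstream gene deoC rose by 0.33 ± 0.10 and deoA, at -0.05 ± 0.08, was not called. The genes of the alternative ribonucleotide reductase, nrdH, nrdI, nrdE and nrdF, rose by 2.05, 2.01, 1.81 and 1.43, and those of the main aerobic enzyme, nrdA and nrdB, at 0.08 and 0.02, were not called. entH, of the enterobactin operon, rose by 2.39 ± 0.16 and ybiX, next to fiu, by 1.22 ± 0.16. The glycine cleavage genes gcvT and gcvP rose by 0.66 and 0.86.

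Among lower genes outside the lists, the biotin synthesis genes bioB, bioF and bioC fell by 1.14, 1.15 and 1.09, the dipeptide transporter genes dppB and dppC by 1.04 and 1.03, and the cytochrome bd-II genes cbdA and cbdB by 1.27 and 1.24. The mechanosensitive channel genes mscS and mscK fell by 1.04 ± 0.07 and 1.12 ± 0.06, and the nucleoside channel gene tsx by 1.18 ± 0.08. yegD, a chaperone-related gene of unknown role, rose from 64.4 ± 0.952 to 245.5 ± 14.5 CPM (1.93 ± 0.07). In wild-type library B, cysP, ydjN, cysU and yeeE measured 42.7, 591, 16.7 and 90.0 CPM, against 3.51 to 4.63, 81.9 to 164.6, 3.19 to 5.48 and 17.0 to 31.4 CPM in the other wild-type libraries.

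With all libraries thinned to the smallest total, 16 iron uptake genes were still called higher, and with a trend on gene length removed the list's median was 1.06, against 1.09 before, so neither depth nor a length trend gives the pattern. A response to low free iron through the small RNA RyhB predicts lower levels of 9 genes such as sodB, ftnA and sdhC. The gene ryhB itself was not among the genes tested. The median of the 9 genes was 0.106 ± 0.128 (SE), with 1 called higher and 1 lower. The SE treats the 9 genes as independent, which sdhC, sdhD, sdhA and sdhB of 1 operon are not. The bound set in advance, a median above 0 against such a response, was passed by less than this SE, which was put into the judgement only after the median was seen, so such a response cannot be told apart from its absence. Strain and culture coincide here, so a difference of iron supply between the cultures stays open and untested.

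As a hypothesis, the lower purR level in the mutant may release the genes that PurR represses. Over 28 such genes, 19 of them members of the lists above, 13 rose and 9 fell, with a median log2 fold change of 0.135, and camera gave p = 0.0177 toward higher levels and p = 0.214 with an estimated correlation, which leaves the question open.

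For the counts of genes, all 35 ways to divide the 8 libraries into 4 and 4 were compared. Only 1, the real one, gave as many as 1456 called genes, and 1 as many as 166 genes at 2-fold. The highest of the others gave 0 and 0. Mixed groups carry the strain difference in their spread, which lowers their counts. At an unadjusted edgeR p under 0.05 the real division gave 1851 genes and the highest other 381. A share of 1 in 35 is the smallest this test can give, so it argues against chance but cannot exclude it. If the replicates are technical, a chance difference between the cultures was not tested. For the 13 lists called by camera, 3 of the 35 gave as many and the highest other gave 14. The others with as many set 3 wild-type libraries and 1 mutant library against 1 and 3, so they carry part of the strain difference. Divisions with equal numbers of both strains in each group gave from 2 to 7 lists, though their spread also holds the strain difference. The count of lists thus leaves chance undecided.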
